A study of Mus musculus with 4 samples.

How the data were processed

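B cells from the spleens of C57BL/6 mice, a widely used inbred strain, were cultured for 4 h with R848 (1 µg/ml), a small molecule that activates the RNA sensors TLR7 and TLR8. Per the labels, the B cells were either alone with R848 (BR) or came from a culture that also held plasmacytoid dendritic cells (BPR). The treatment protocol field of all 4 samples reads both with and without R848, while the treatment tag and the source names give R848 for each. All 4 were taken as treated, and this conflict was not resolved. Plasmacytoid dendritic cells (pDCs) are immune cells known for making large amounts of type I interferon. RNA from 200 sorted cells per library was amplified with a strand-preserving SMARTer kit and sequenced. The 4 libraries form 2 groups of 2, which the series' design text calls biological duplicates, and samples were grouped by those labels alone. Whether cells of different libraries came from different mice or wells is not given in the sources used here, so p-values of single genes measure the spread between these libraries.

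The deposited values are RPKM (read numbers scaled to gene length and to the reads counted in the library), 1 column per library for 55536 Ensembl gene IDs. Per the submitters' processing notes, Trimmomatic 0.38, HISAT2 2.1.0, featureCounts 1.6.0 and the build mm9 were used, with no role or order given. All 55536 IDs matched GENCODE release M21, which is made for GRCm38 and not for mm9. RPKM multiplied by the merged exon length from that release summed to 1e+06 in each library. Symbols, gene types and coordinates were taken from that release, and coordinates are GRCm38, counted from 1. The conflict between the build named in the notes and the build of the annotation was not resolved. Whether reads or fragments were counted, and whether the strand was used, are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart.

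In each library 100% of values were whole multiples of the value of 1 read, within 0.01 of a read, which gave back the reads behind each value. The reads counted were 31334530 and 26036251 in BR replicates 1 and 2, and 20891155 and 27185213 in BPR replicates 1 and 2. Because amplified reads without molecular identifiers are not independent molecules, intervals and floors cover counting error only. The floor of a gene with no read was set at 3 reads and converted to RPKM for each library. Exact 0 values were checked: 0 of 16 widely used genes were at 0 in any library, and 1 of 132 proteasome, complex I and mitochondrial ribosome genes with a mean of 5 RPKM or more was.

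A count-based test had been laid down for the case that the files held counts, with limma on log2 values in its place for normalized values. As the deposited unit is RPKM, the comparison used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with default empirical Bayes moderation and no block. Genes with at least 1 RPKM in at least 2 libraries were tested, which left 10232 genes. Differences are BPR minus BR on that scale, which understates changes of low genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. The fitted prior had 2.43 degrees of freedom and an SD of 0.352, added to 2 residual degrees of freedom. Ratios of mean RPKM are printed only where every library had at least 10 reads of the gene. Tables and resampling were done with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

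The fit was tested on simulated data for the 10232 genes, with the spread drawn from the fitted prior. It called 0% of 50 genes changed by a log2 difference of 1, 2% of 50 changed by 2, 58% of 50 changed by 4 and 90% of 50 changed by 6. Of 10032 genes simulated without a change it called 1. Changes were simulated only as rises in genes with a middle level in BR. In the real data 32 of the 85 genes called higher had no read in BR, and all 10 called lower had none in BPR. The simulated rates do not describe calls of that kind.

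Before the data were examined, 29 gene lists were fixed. They cover interferon responses, B cell functions, growth and stress, and markers of other cells a spleen sort could hold. Lists with at least 3 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over 25 lists. With that preset its p-values rest on the spread across genes and do not measure the spread between libraries. Camera was repeated with an estimated correlation, where its p-values rest on the 2 residual degrees of freedom. As a further test, fry asked whether a list's genes moved, on balance, one way. Each list's members were also counted after adjustment over the list alone.

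The genes named were chosen by a rule fixed before the data were examined. The rule took the 10 largest called differences in each direction with non-overlapping groups and a mean of at least 10 CPM in the higher group, leaving out unnamed models and immunoglobulin segments. A direction with fewer than 5 such genes was filled to 5 with the smallest p. It added up to 3 members of each list with the smallest p and at least 10 CPM, and 15 genes named in advance, among them Ms4a1, Cd79a, Tlr7, Ifnar1, Cd69, Cd86, Prdm1, Il6, Il10, Siglech, Irf7, Isg15 and Mx1. Genes named outside the rule are marked as such, and some genes that the rule takes are not reported here.

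Other settings laid down in advance were median-of-ratios and upper-quartile scaling, limma-voom on the recovered reads, no filter, a filter of 10 CPM in 2 libraries, removal of immunoglobulin genes, the replicate number as a block, leaving out each library, and other thresholds. Pseudocounts of 0.1 and 0.25, a variance prior with a trend, protein-coding genes only and genes of at least 300 bases only were chosen after seeing the data. So were lists without the members of the type I interferon-stimulated and the interferon-gamma-linked list. Members of multigene families share near-identical copies (Ifit, Slfn, Gbp, Ifi200, Oas, Trim30, Phf11, H2-T, Ifitm and histone genes), and how reads that fit several copies were treated is not given in the sources used here. Values of single members are therefore uncertain.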

Results

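Gene expression was measured by RNA-seq in splenic mouse B cells after 4 h with R848, either alone (BR, n = 2) or taken from a culture that also held plasmacytoid dendritic cells, or pDCs (BPR, n = 2). The libraries held 20891155 to 31334530 counted reads. Between 83.5% and 85.3% of reads fell in protein-coding genes, and mitochondrial ribosomal RNA took 7.66% to 11.2%. A gene with at least 1 read was seen for 13485 and 13860 genes in the BR libraries and for 15191 and 15647 genes in the BPR libraries. Across 10232 genes, which are not independent replicates, log2 values correlated with r = 0.894 between the BR libraries and 0.876 between the BPR libraries. Between groups r lay between 0.823 and 0.858. A single 57-base small RNA gene, Gm23935, named here after its values were seen, took 1.51% to 1.92% of reads.

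The design compares B cells under R848 with and without pDCs in the culture, and holds no untreated library, so a response to R848 itself cannot be measured. The main difference was a rise of type I interferon-stimulated genes in BPR, the set that cells switch on when interferon binds its receptor. Of 61 tested members of this list, 39 were called higher in BPR and 0 lower, and all 61 had a positive difference. Mx1 transcripts had 0 reads in both BR libraries and 134.9 ± 1.57 RPKM (SD, n = 2) in BPR. Irf7, the transcription factor that amplifies interferon production, was 47.6 times higher by mean RPKM. In all, limma called 85 genes higher and 10 lower in BPR, and 571 and 402 genes had an unadjusted p under 0.05. limma called neither Ms4a1 nor Cd79a, and Siglech, a surface receptor of pDCs, had 0 reads in all 4 libraries.

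**Figure D1:**
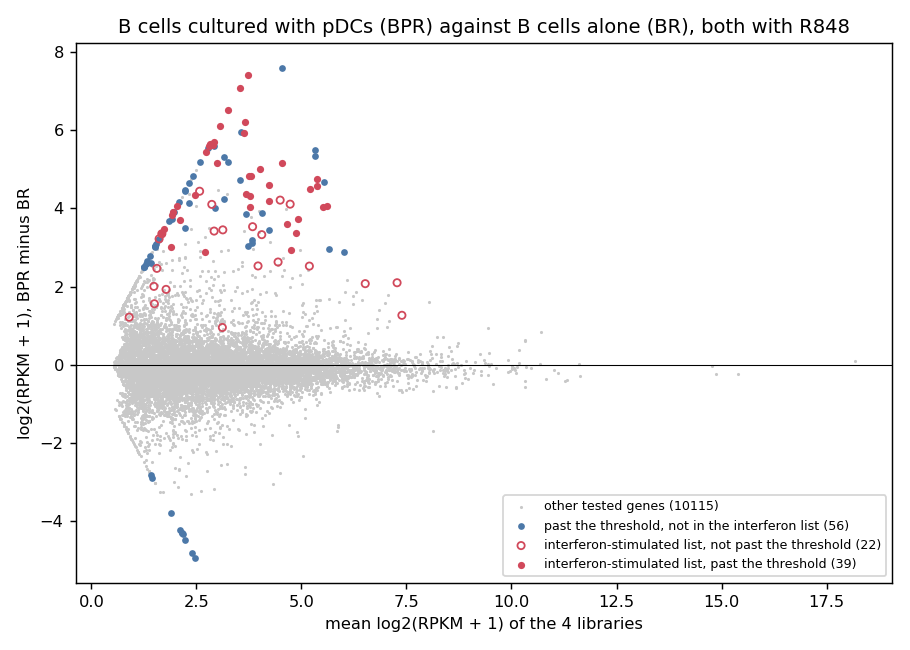
Each point is 1 of the 10232 tested genes, with its mean log2(RPKM + 1) over the 4 libraries on the x axis and the difference BPR minus BR on the y axis. Filled dots are called genes, 85 above 0 and 10 below, red in the interferon-stimulated list and blue outside it. Open circles are list members that did not pass.

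These counts rest on all 4 libraries and on the filter: without BR replicate 1, BR replicate 2, BPR replicate 1 or BPR replicate 2 in turn, and with no filter, limma called 0 genes in either direction. The 85 genes had positive differences in each of those fits. They were chosen from these same libraries for log2 differences of at least 2.505, so a kept sign gives no support of its own. With no filter, genes with an unadjusted p under 0.05 numbered 805 higher and 641 lower. limma-voom called 124 genes higher and 4 lower, of which 33 and 0 were among the genes called in the main fit. At an unadjusted p under 0.05 limma-voom gave 402 genes higher and 415 lower, so the main fit's excess of higher genes at that cut was not kept.

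By the rule for named genes, which leaves out unnamed models, the largest called differences were in genes of the antiviral response. Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731), whose family binds viral RNA, had 0 and 0.022 RPKM in the BR libraries and 172.2 ± 19.4 RPKM (SD, n = 2) in BPR. Its log2 difference was 7.42 (SE 0.27, limma adjusted p = 0.0199). Mx1 (ENSMUSG00000000386, chromosome 16, 97447035 to 97462907) differed by 7.09 (SE 0.26, limma adjusted p = 0.0199), and 3 reads would have stood for 0.0253 and 0.0304 RPKM in the BR libraries. Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009) had 0 reads in BR and 115.9 and 70.3 RPKM in the BPR libraries. Usp18 (ENSMUSG00000030107, chromosome 6, 121245906 to 121270917), which removes ISG15 from proteins and dampens interferon receptor signalling, had 0 reads in BR and 69.1 ± 13.7 RPKM (SD, n = 2) in BPR. Rtp4 also had 0 reads in BR and reached 48.8 ± 3.18 RPKM in BPR. Ifit2, Zbp1, Rsad2, Slfn5 and Mx2 completed the 10 genes that the rule took, with log2 differences of 6.22, 5.93, 5.71, 5.64 and 5.60. The annotation types Mx2 as a polymorphic pseudogene. Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), a ubiquitin-like protein, rose from 2.93 ± 1.39 to 90.95 ± 13.84 RPKM (SD, n = 2), with a limma adjusted p of 0.0278. Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481) rose from 1.91 ± 0.88 to 90.9 ± 17.8 RPKM (SD, n = 2), with a limma adjusted p of 0.0232.

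**Figure D2:**
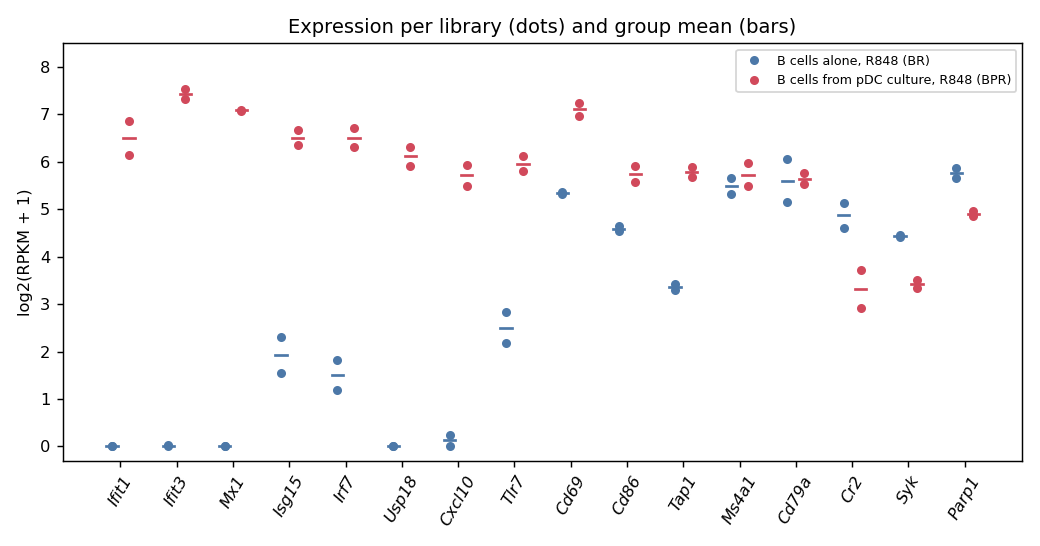
Dots are log2(RPKM + 1) of 16 genes in each of the 4 libraries and bars are group means, with BR to the left and BPR to the right of each gene. Mx1, Ifit1 and Usp18 sit at 0 in both BR libraries, and Ms4a1 and Cd79a overlap between groups.

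As a list, the type I interferon-stimulated genes had a median log2 difference of 4.05, which ran from 3.70 to 5.45 over 16 alternatives. Adjusted over the list alone, 60 of the 61 were higher, and limma-voom called 27. camera with the preset correlation called the list higher (adjusted p = 3.05e-84), but not with an estimated correlation (adjusted p = 0.139). fry, which does not compare the list with other genes, gave an adjusted p of 0.00714. Its adjusted p was 0.00602 for both the GBP/IRG and the nucleic acid sensing list. It was 0.0247 for MHC class I, 0.0323 for cytokine and 0.0448 for JAK-STAT genes. The apoptosis and class switching lists did not pass by fry (adjusted p = 0.209 and 0.186). None of the 8 lists that camera called held its call with an estimated correlation, where it has only 2 residual degrees of freedom. For the GBP/IRG, nucleic acid sensing, MHC class I and cytokine lists that correlation was -0.028, -0.047, -0.026 and -0.039, below the preset 0.01. In the other called lists it was above 0.01. The losses alone therefore do not show that correlated members made the calls. No fold is given for the 11 members with no read in a group.

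In the list of GBP, IRG and other interferon-gamma-linked genes, 5 of 26 tested members were called higher, 19 when adjusted over the list alone, and 10 by limma-voom. Their median was 2.13 (camera adjusted p = 2.67e-23, and adjusted p = 0.139 with an estimated correlation). Gbp4 and Irgm2, GTPases that act against intracellular microbes, were 18.9 and 34.3 times higher by mean RPKM, and Irgm2 was 56.2 times higher without BR replicate 1. Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), a chemokine that attracts T cells, had 0 and 0.188 RPKM in the BR libraries and 52.2 ± 11.7 RPKM (SD, n = 2) in BPR. In the nucleic acid sensing list, 6 of 19 members were called higher, 11 adjusted over the list alone and 7 by limma-voom, with a median of 2.29 (camera adjusted p = 5.6e-11, and adjusted p = 0.146 with an estimated correlation). Ddx58, which encodes the RNA sensor RIG-I, was 30.7 times higher (limma adjusted p = 0.0232).

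Tlr7 (ENSMUSG00000044583, chromosome X, 167304929 to 167330558), the receptor that R848 acts on, rose from 4.82 ± 1.81 to 61.6 ± 9.72 RPKM (SD, n = 2), a log2 difference of 3.45 (SE 0.36, limma adjusted p = 0.0447). It was the 1 called member of 32 in the TLR7 and NF-kB list, also when adjusted over the list alone. The list's median was 0.11 and camera did not call it (adjusted p = 0.126). The list passed in 4 of 16 alternatives, with adjusted p between 0.0151 and 0.640, and its median was -0.02 without BPR replicate 2. Myd88, the adaptor used by TLR7, was at 13.6 ± 2.68 RPKM in BR and 30.3 ± 6.28 RPKM in BPR and did not pass (limma adjusted p = 0.369). Tlr9 did not pass either (limma adjusted p = 0.767).

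Of the interferon receptor and JAK-STAT genes, 2 of 21 were called higher, Usp18 among them, 5 adjusted over the list alone and 2 by limma-voom. The median was 0.22 and the mean 0.86 (camera adjusted p = 0.000191, and adjusted p = 0.530 with an estimated correlation). Stat2 was at 3.38 ± 1.76 and 47.8 ± 6.18 RPKM (SD, n = 2) and missed the threshold (limma adjusted p = 0.0549), but passed it in 6 of 16 alternatives, with adjusted p between 0.000126 and 0.491. Ifnar1, a chain of the type I interferon receptor, differed by 0.22 (95% interval -0.56 to 0.99). Among MHC class I presentation genes, 2 of 25 were called higher, 6 adjusted over the list alone and 5 by limma-voom, with a median of 0.55 (camera adjusted p = 3.8e-07, and adjusted p = 0.165 with an estimated correlation). These were H2-T24, 20.2 times higher, and Nlrc5, an activator of MHC class I genes, 9.95 times higher. Tap1, which carries peptides for loading, was at 9.31 and 54.4 RPKM and missed the threshold (limma adjusted p = 0.0549), but passed it in 4 of 16 alternatives, with adjusted p between 0.000121 and 0.494. Of cytokine and chemokine genes, 2 of 17 were called higher, Cxcl10 and Csf1, 4 adjusted over the list alone and 0 by limma-voom (median 0.47, camera adjusted p = 0.000191, and adjusted p = 0.241 with an estimated correlation). Csf1, a growth factor of macrophages, was at 0.0906 and 0.778 RPKM in the BR libraries and 14.9 ± 1.74 RPKM (SD, n = 2) in BPR (limma adjusted p = 0.0447). The ratio of its means was 34.2, but 19.1 without BR replicate 1 and 164.1 without BR replicate 2.

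**Figure D3:**
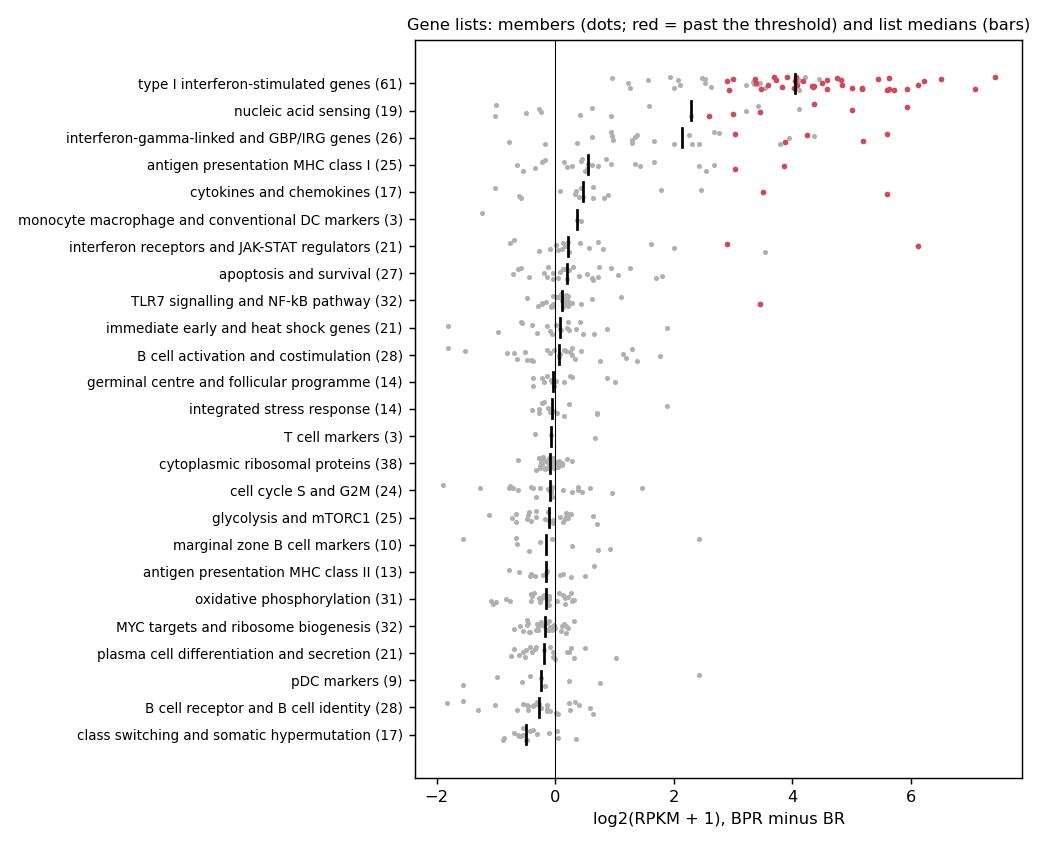
Each row is a gene list with at least 3 tested members, each dot a member's log2 difference (BPR minus BR) with called members in red, and each bar the list's median. The type I interferon-stimulated genes have the highest median, 4.05, and the class switching list the lowest, -0.50.

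In 2 lists that camera called, no single member passed. Apoptosis and survival genes had a median of 0.20 over 27 members (camera adjusted p = 0.0198, and adjusted p = 0.572 with an estimated correlation), with 0 called by limma, 3 higher at an unadjusted p under 0.05 and 1 called higher by limma-voom. Casp4, an inflammatory caspase, was at 10.4 ± 2.80 and 38.2 ± 2.98 RPKM (limma adjusted p = 0.139), and passed in 3 of 16 alternatives, with adjusted p between 0.00589 and 0.670. Class switching and hypermutation genes had a median of -0.50 over 17 members, 3 of them positive (camera adjusted p = 0.0166, and adjusted p = 0.530 with an estimated correlation). limma and limma-voom called 0 of these, and 2 were lower at an unadjusted p under 0.05. Parp1, a DNA repair enzyme, was at 53.8 ± 5.85 and 29.0 ± 1.59 RPKM (limma adjusted p = 0.409). Without BR replicate 2 or BPR replicate 2 camera did not call the class switching list (adjusted p = 0.158 and 0.111) or the apoptosis list (0.177 and 0.115), and with no filter it did not call the apoptosis list (0.0622). Over all 16 alternatives the adjusted p ran from 0.000386 to 0.158 and from 0.00288 to 0.177.

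Among B cell identity genes, Ms4a1 differed by 0.24 (95% interval -0.64 to 1.12) and Cd79a by 0.04 (-1.04 to 1.13). Ms4a1 was at -0.0035 without BPR replicate 1, and Cd79a at -0.41 without BR replicate 2 and at -0.07 without BPR replicate 2. Of 28 identity genes, limma called 0, and 2 were lower at an unadjusted p under 0.05. The list's median was -0.28 and camera did not call it (adjusted p = 0.253), while fry gave an adjusted p of 0.0448. camera passed in 2 of 16 alternatives, limma-voom and no filter, with adjusted p between 0.0197 and 0.352. Syk, a kinase of B cell receptor signalling, was at 20.6 ± 0.40 and 9.73 ± 0.88 RPKM, and Cr2, a complement receptor, at 28.8 ± 7.51 and 9.33 ± 3.93 RPKM (SD, n = 2), both with a limma adjusted p of 0.325. limma-voom called both lower (adjusted p = 0.0371 and 0.0235), the only 1 of 16 alternatives that did for either. Their adjusted p ran up to 0.845 and 0.879.

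Of 28 activation and costimulation genes, limma called 0, with 4 higher and 1 lower at an unadjusted p under 0.05, and limma-voom called 3 higher. The median was 0.07, with a camera adjusted p of 0.253 that passed in 1 of 16 alternatives, limma-voom, and ran from 0.0197 to 0.714. It was -0.05 without BR replicate 1. Cd69, an early activation marker, was at 39.5 ± 0.77 and 137.4 ± 18.5 RPKM (SD, n = 2, limma adjusted p = 0.114). Cd86, a costimulatory ligand, was at 23.2 ± 1.14 and 53.0 ± 8.92 RPKM (limma adjusted p = 0.292). Cd274, which encodes PD-L1, was at 13.7 ± 0.92 and 37.8 ± 9.18 RPKM (limma adjusted p = 0.239). limma-voom called these 3 (adjusted p = 9.85e-05, 0.0273 and 0.0338), and Cd69 passed in 3 of 16 alternatives and the others in 1. Their adjusted p ran up to 0.631, 0.845 and 0.824.

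Il6 was at 2.366 and 1.598 RPKM in the BR libraries and 8.85 and 0 in the BPR libraries, so the BPR libraries disagreed. Prdm1, a regulator of plasma cell formation, was at 2.39 and 1.98 RPKM in BR and 0.0257 and 3.79 in BPR. Il10 had 12 reads in BPR replicate 1 and 0 in the other libraries.

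Other lists were not called by camera in the fit of all 4 libraries. Medians were -0.19 for 21 plasma cell genes (adjusted p = 0.566), -0.16 for 10 marginal zone genes (0.913), -0.16 for 13 MHC class II genes (0.733) and -0.09 for 24 cell cycle genes (0.733). The 32 MYC target and ribosome biogenesis genes had a median of -0.17 (0.253), 25 glycolysis and mTORC1 genes -0.11 (0.733), 31 oxidative phosphorylation genes -0.17 (0.253) and 21 immediate early and heat shock genes 0.08 (0.479). The MYC target list passed in 3 of 16 alternatives (limma-voom, no filter and without BR replicate 1), with adjusted p between 0.00849 and 0.981. Oxidative phosphorylation and ribosomal proteins passed in 1 each, no filter, with adjusted p between 0.0190 and 0.604 and between 0.0444 and 0.981. Medians were -0.04 for 14 germinal centre genes (0.603), -0.09 for 38 ribosomal protein genes (0.603) and -0.06 for 14 integrated stress response genes (0.566), and these 3 turned positive with median-of-ratios scaling, at 0.06, 0.02 and 0.05. Atf3, in the stress lists, was at 4.54 ± 0.37 and 19.9 ± 5.75 RPKM (limma adjusted p = 0.136), and passed in 1 of 16 alternatives, with adjusted p between 0.0322 and 0.688.

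Most markers of other cells were under 1 RPKM. Siglech had 0 reads in all 4 libraries, where 3 reads would have stood for 0.0283 to 0.0424 RPKM. Of 29 pDC markers 18 were under 1 RPKM in every library, and the 9 tested had a median of -0.25 (camera adjusted p = 0.940). Tcf4, a transcription factor of pDCs that B cells also express, was at 2.85 ± 0.95 and 5.38 ± 0.74 RPKM (limma adjusted p = 0.599). Plac8, on the pDC and the marginal zone lists, was at 3.35 and 0 RPKM in the BR libraries and 23.6 and 4.07 RPKM in the BPR libraries, a log2 difference of 2.42 (SE 1.08, limma adjusted p = 0.606). Of 20 T cell markers 16 were under 1 RPKM in every library, as were 11 of 13 NK cell markers, 18 of 21 monocyte and conventional dendritic cell markers, 14 of 15 neutrophil and mast cell markers and 11 of 13 erythroid and platelet markers. The 3 tested T cell markers had a median of -0.08 (0.940) and the 3 tested monocyte and dendritic cell markers 0.36 (0.989). The 2 tested erythroid and platelet markers had a median of 0.17, and no NK or neutrophil marker was tested. Of 20 type I and III interferon genes, 18 were under 1 RPKM in every library. Ifnb1, named outside the rule, had 0 reads in all 4.

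Of the 85 genes called higher, 63 reached a mean of 10 CPM in the higher group and 11 were under 300 bases long. They held 56 protein-coding genes, 12 pseudogenes, 7 small RNA genes and 2 immunoglobulin segments. The 10 genes called lower had no read in either BPR library, and 0 of them reached 10 CPM, so the rule named none. They comprised 6 small RNA genes, 2 pseudogenes, 1 immunoglobulin segment and 1 other protein-coding gene, Ifitm2, named here after its values were seen. Ifitm2 was at 6.24 and 5.98 RPKM in BR and 0 in BPR (limma adjusted p = 0.0355), and it lies near related copies. The 5 genes that filled the rule in this direction did not pass in the fit of all 4 libraries, but each passed in some alternatives. Hist1h4m, a histone H4 gene, was at 73.7 ± 8.89 and 13.8 ± 1.77 RPKM (SD, n = 2, limma adjusted p = 0.0663), and passed in 3 of 16 alternatives, with adjusted p between 0.00859 and 0.523. Trim32, D17H6S53E, Zscan2 and Naa38 had log2 differences of -2.07, -2.08, -2.11 and -2.20 with limma adjusted p of 0.0738, 0.0834, 0.102 and 0.102. They passed in 3 of 15, 2 of 16, 1 of 16 and 1 of 16 alternatives, with lowest adjusted p of 0.0270, 0.0129, 0.0165 and 0.0158 and highest of 0.671, 0.611, 0.695 and 0.639.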

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

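The pseudocounts, the trended prior, the protein-coding and 300-base subsets and the lists without members of the interferon lists were chosen after seeing the data. The 85 genes higher in BPR were positive in each alternative for all of them that were tested there. Their choice from these same libraries for large differences made that all but certain. With median-of-ratios scaling, upper-quartile scaling or removal of immunoglobulin genes, 83 or more were called again. Over all alternatives, 1123 values of named genes kept direction and side of the threshold, 154 fell below it, 32 passed it and 11 changed sign. Only the 21 named genes that were called could fall below it. Isg15, Zbp1, Ifit2 and Csf1 passed in 7 of 16 alternatives and Tlr7 in 8. Mx1, Ifit1 and Ifit3 passed in 9, and Irf7, Ddx58, Gbp4 and H2-T24 in 10. For lists, 363 values kept direction and side, 5 fell below the threshold, 12 passed it and 17 changed sign. Calls of single genes depend on the filter and on having 4 libraries. Unless said otherwise, the cause of a change was not tested.

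Genes higher numbered 85, but 0 with no filter, 154 with at least 10 CPM in 2 libraries, 129 with a trended prior and 137 at an adjusted p under 0.1. Genes lower numbered 10, but 4 with limma-voom, 0 with no filter, 33 with a pseudocount of 0.1, 4 among protein-coding genes, 5 among genes of at least 300 bases and 17 at an adjusted p under 0.1. Interferon-stimulated genes higher numbered 39, but 0 with no filter and 25 with a pseudocount of 0.25. With no filter 21319 genes were tested, and limma gave 805 higher and 641 lower at an unadjusted p under 0.05. Lists higher numbered 7 and lists lower 1, but 0 and 0 with an estimated correlation, and lists lower numbered 3 with limma-voom and 5 with no filter.

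Leaving out each library gave 0 to 0 genes higher, 0 to 0 lower, 0 to 0 interferon-stimulated genes and 0 to 2 lists lower. There the lone library is assumed to vary like the other group, and 1 residual degree of freedom fewer is left. The median log2 difference over all tested genes ran from -0.12 to -0.04 in these fits. Directions changed there for values that did not pass in the full data. Log2 differences ran from -0.76 to 0.0033 for Foxo1, -0.0065 to 0.73 for Zbtb46, -1.56 to 1.74 for Il6, -0.41 to 0.49 for Cd79a, -1.63 to 0.59 for Prdm1 and -0.0035 to 0.48 for Ms4a1. List medians ran from -0.023 to 0.16 for TLR7 and NF-kB genes, -0.052 to 0.19 for B cell activation, -0.088 to 0.10 for germinal centre, -0.56 to 0.070 for marginal zone and -0.32 to 0.19 for MHC class II genes. They ran from -0.068 to 0.20 for immediate early, -0.073 to 0.0050 for stress response, -0.52 to 0.056 for pDC, -0.39 to 0.47 for T cell and -0.0065 to 0.28 for monocyte and dendritic cell genes.

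Il6 was -3.47 with limma-voom, -1.11 with a pseudocount of 0.1 and -0.54 with 0.25. With median-of-ratios scaling the germinal centre list was at 0.060, ribosomal proteins at 0.016 and the stress response list at 0.046.

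With the replicate number as a block, limma called 0 genes higher, 0 lower and 0 interferon-stimulated genes, with 579 higher and 367 lower at an unadjusted p under 0.05. The fit without a block had been laid down in advance, because the labels state no pairing. Deviations of same-numbered libraries correlated at -0.0236 across genes. With 2 libraries per group this cannot show whether the numbers pair the libraries. The block uses up 1 of 2 residual degrees of freedom.

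A planned count-based Wald test and trimmed-mean scaling were not run. The deposited unit is RPKM, and the only count-based fit run on the recovered reads was limma-voom. Without members of the type I interferon-stimulated and interferon-gamma-linked lists, camera called the nucleic acid sensing, cytokine, MHC class I, apoptosis and class switching lists (adjusted p = 0.00855, 0.00855, 0.0106, 0.0291 and 0.0266). It did not call the JAK-STAT list (adjusted p = 0.198). With an estimated correlation camera called none of them (adjusted p = 0.574, 0.574, 0.574, 0.770 and 0.770 for those called before). Called genes stayed in some of the lists, among them Tlr7 and Ddx60 in nucleic acid sensing and H2-T24 in MHC class I. Whether the genes left in also respond to interferon was not tested. The calls therefore do not show a shift apart from the interferon response. In the simulation a log2 difference of 2 was called for 2% of genes with a middle level in BR. Smaller differences of such genes were therefore mostly not detectable by the main fit. The limit is not one of the libraries alone: limma-voom called Cd69 and Syk, whose main-fit differences were 1.77 and -1.01.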

Other observations

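The tests of pDC carry-over and of depth as a source of detected genes, the histone set with its list tests, and the choice of the genes in the next paragraph and of Ccr9, Cox6a2, Mctp2 and Ifnk came after the results were seen.

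Of the 56 protein-coding genes called higher, 9 were in no list. Ifi206 and Ifi208, DNA-binding PYHIN proteins on chromosome 1, were at 8.25 ± 0.28 and 235.5 ± 32.2 RPKM and at 1.24 ± 0.17 and 58.5 ± 0.46 RPKM (SD, n = 2) in BR and BPR. Rnf213, a large ubiquitin ligase, was at 5.04 ± 0.91 and 276.2 ± 90.8 RPKM, 54.8 times higher (limma adjusted p = 0.0230). Trafd1 and Trim34a were 11.5 and 10.6 times higher. Ifi47 was at 0.968 and 0 RPKM in the BR libraries and 56.5 ± 19.2 RPKM (SD, n = 2) in BPR. Sdc3, a cell-surface heparan sulphate proteoglycan, was at 0.0639 and 0 RPKM in the BR libraries and 12.9 ± 3.44 RPKM in BPR (limma adjusted p = 0.0295). BC147527 and Gm12185 had 0 reads in BR. Ifna13, which is on the interferon gene list and was not tested, had 86 reads in BPR replicate 2 and 0 in the other libraries.

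The interferon-stimulated genes were higher in BPR, and 41 list members were called with median-of-ratios scaling. Its factors were 1.04 and 1.066 in BR and 1.004 and 0.9578 in BPR, so the number called could hardly have fallen. Factors this alike argue against scaling as the source of a median log2 difference of 4.05. Carried-over pDCs would bring their abundant transcripts, but 0 percent of 20 pDC markers under 1 RPKM in both BR libraries reached 1 RPKM in both BPR libraries, Siglech had 0 reads and the cells had been sorted. In the other direction, 2 of the 20 reached 1 RPKM in 1 BPR library, Cox6a2 (0.0939 and 0 RPKM in BR, 0 and 4.54 in BPR) and Mctp2 (0.494 and 0.295 in BR, 2.104 and 0.477 in BPR), Ccr9 was at 0.0933 and 0.0374 RPKM in BR and 0.611 and 0.197 in BPR, and Plac8, outside those 20 markers, was at 3.35 and 0 RPKM in BR and 23.6 and 4.07 in BPR. Interferon made by the B cells themselves remains open: 0 interferon genes passed 1 RPKM in both BPR libraries while under 1 in both BR libraries. However, Ifnk was at 1.67 and 0 RPKM in BR and 3.45 and 3.02 in BPR. Ifna13 had reads in BPR replicate 2 only, the library in which Cox6a2 was at 4.54 RPKM. Transcripts at earlier times were not measured. A response of B cells to interferon from pDCs is a hypothesis that may account for the pattern, and it was not tested, since no libraries with the interferon receptor blocked or absent were analysed here.

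Histone genes of the replication-dependent clusters tended to be lower in BPR: 35 of 44 were negative, with a median of -0.74 (bootstrap interval over genes -1.19 to -0.53), though limma called 0. The set was picked after its members were seen low, and its genes are clustered near-copies: camera gave p = 6.09e-07 with the preset correlation but p = 0.148 with an estimated correlation, and fry p = 0.103, so a shift of the set was not shown. The median ran from -1.12 to -0.48 as libraries were left out. Fewer cells in S phase could lower them, but 11 S phase genes had a median of -0.1178 (-0.376 to 0.376), which leaves it open. Lower yield of RNA without a poly(A) tail is open too: 131 small RNA genes had a median of -0.06833 (-0.230 to 0.146), and it ran from -0.63 to 0.57 as libraries were left out.

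More genes had a read in BPR. Depth does not account for it, since after thinning to the shallowest library the lowest BPR count lay 1511 genes above the highest BR count (13258 and 13680 against 15191 and 15429). Capture of more distinct molecules could do so, but the share of genes at 10 RPKM that were at 0 in the replicate was 0.109% (Wilson 95% interval 0.0552 to 0.215) in BR and 0.126% (0.0664 to 0.240) in BPR, a difference of 0.01724, so it cannot be told apart from other sources. Genes with reads in both BPR libraries and no BR library numbered 712, of which 396 were protein-coding, against 299 and 138 in the other direction.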
